A study of Rattus norvegicus with 2 samples.

How the data were processed

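RNA of skeletal muscle from streptozotocin-treated diabetic rats was hybridised to Illumina rat bead arrays, in which each probe is a 1-colour measurement of a transcript. There were 2 samples with 1 array each, labelled Mock and EA (electroacupuncture). Per the labels, biotinylated cRNA was made from total RNA with an Ambion kit for Illumina arrays. Both samples carry the same treatment text, so what the Mock animals received is not stated, and neither is the number of rats behind each sample.

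The deposited non-normalized table holds the probe intensity on a linear scale and, per the file headers, a detection p-value for each of 22523 probes on each array. The intensities had not been background-subtracted, since the lowest were 65.6 on the Mock array and 64.4 on the EA array. The detection p-values moved in steps of 0.00121, and each p-value column was matched to its array because it fell as that array's signal rose. The scanner software, the number of beads and bead-level errors are not given in the sources used here, so an error per probe could not be computed. The deposited series table holds a second set of intensity values made by the authors from the same arrays. Its values rank the probes exactly as the non-normalized ones do (Spearman rho = 1 on both arrays, across probes), so its direction is the same. Ranks do not show the scale, which was taken as linear given the size of the values. The sorted values of its columns differed by at most 0.858%, with medians of 137.3 and 137.5. The upper quartile was 302.2 in both columns, against 197.7 if these arrays alone had been quantile normalized, so where that shared distribution came from stays unknown. That table was used as an alternative.

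From the non-normalized intensities, background was corrected with limma's nec function, which fits a normal-exponential model with the background taken from the detection p-values. An offset of 16 was added, the arrays were quantile normalized, and values were put on the log2 scale. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A probe was called detected at a detection p under 0.01. Genes were named through the platform annotation, which can be old, and symbols were updated by gene identifier and then by accession against the RefSeq gene table of assembly GRCr8. Of the probes, 13793 had 1 gene symbol, none had several, and 8730 had none here. Of the named probes, 13752 matched by gene identifier, 5 by accession, and 36 kept the platform's symbol. The update changed 4 symbols. The probes covered 13337 genes, and a gene with several probes (425 genes) took its brightest probe. No genome coordinates were used, as the build behind the probes is not given in the sources used here.

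Each gene's value is the log2 signal on the EA array minus that on the Mock array. With 1 array per group there is no replicate check, no standard error and no p-value for any difference, and the number of arrays limits the precision. The only internal measure of technical scatter came from 60 pairs of probes for the same gene, both detected on both arrays. The difference between the arrays scattered between such probes with an SD of 0.25 per probe on the log2 scale, and the median gap within a pair was 0.21. Of those pairs, 55% had the same sign. This scatter includes cross-hybridisation and isoform differences and leaves out the variation between animals. A gene detected on only 1 array was given a lower bound, made from the bright array's signal over the higher of the dim probe's own signal and the lowest signal among the detected probes of the dim array, all as normalized log2 values.

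Before the data were examined, 29 gene lists were fixed. They were insulin signalling, AMPK and calcium signalling to glucose uptake, MAP kinase signalling, glycolysis and glycogen, oxidative phosphorylation, fatty acid uptake and oxidation, immediate early genes, heat shock proteins and chaperones, oxidative and integrated stress, glucocorticoid-responsive genes, atrophy and proteolysis, circadian clock, cytokines and inflammatory response, interferon response and antigen presentation, slow fibre contractile genes, fast fibre contractile genes, denervation and neuromuscular junction, myogenic and satellite cell genes, angiogenesis and hypoxia, cytosolic ribosomal proteins, reference genes, and markers of erythrocytes, macrophages and leukocytes, neutrophils, adipocytes, endothelium, fibroblasts and matrix, Schwann cells and nerve, and smooth muscle and pericytes. For each list the median over members detected on both arrays was taken, with an order-statistic 95% interval that describes the spread of members and not of animals. Its percentile among 10000 random lists of the same size, matched on signal in 20 bins, describes these arrays only.

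The rule for naming genes was also fixed in advance. It took the 12 highest and the 12 lowest differences among genes detected on both arrays with a mean signal in the upper 50% of those genes, and the 4 highest and 4 lowest of the remaining genes detected on both arrays. It also took the 2 highest and 2 lowest members of each list, 10 genes of insulin-stimulated glucose uptake (Insr, Irs1, Irs2, Pik3r1, Akt1, Akt2, Slc2a4, Tbc1d4, Hk2 and Gys1), and the 5 largest lower bounds in each direction. Predicted loci were left out of the parts that rank all genes. Not every gene the rule took is named. Other genes named in the text were chosen after their values were seen, and the text says so.

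The normalization was tested on simulated data for the EA minus Mock comparison, with 22523 probes, added noise of SD 0.15 and 200 changed probes. Of planted 2-fold increases, 28% came out at 2-fold or more, with a median log2 difference of 0.88, so counts at this threshold miss many changes of that size. Only probes still detected on both simulated arrays were scored. These were 50 for each increase, 44 for the decrease to 0.5 of the level and 39 for the 4-fold decrease. Among scored probes, planted 4-fold increases and decreases all passed 2-fold, with medians of 1.93 and -1.85. Of the scored decreases to 0.5 of the level, 50% were recovered, with a median of -1.00. Decreases that fell below detection are left out of these shares. Of unchanged probes detected on both, 0.066% passed 2-fold. The noise was a chosen value without variation between animals, and the real differences had an SD of 0.43 across genes. This share is therefore not a false-positive rate for the real counts. The list step was tested on 5047 genes with 200 random lists per setting. With no shift planted, 7.5% of lists fell outside the central 95%. A planted shift of 0.2 was found in 49.5% of lists of 12 genes and 79% of lists of 25 genes, and a shift of 0.5 in all of them.

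The alternatives were no background correction, an offset of 50, scaling to the 75th percentile of detected probes, cyclic loess, the authors' deposited normalized values, the mean of all probes of a gene, a detection p under 0.05, no detection filter, the upper 50% of signals, a threshold of 1.5-fold, list members detected on at least 1 array, and random lists without matching. Centring the 75th percentile scaling on the median gene, leaving Egr2 out of the Schwann cell list, setting list members detected on 1 array at their lower bound, and recomputing the lower bounds under other backgrounds and scalings were chosen after seeing the data.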

Results

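The series compared skeletal muscle from male Wistar rats, 8 to 10 weeks old, made diabetic with streptozotocin, a toxin of the insulin-producing beta cells. One sample was labelled Mock and the other EA, for electroacupuncture, in which current is passed through acupuncture needles. The needles stood at ST36 (Zusanli), a point on the lower leg, and 5 min of needling preceded 60 min of stimulation at 15 Hz and 10 mA. How long after stimulation the muscle was taken is not stated. The stated purpose was to screen for intracellular signalling pathways of the blood-glucose-lowering activity. Each group had 1 array, so none of the differences below has a replicate check, and EA against Mock cannot be told apart from any other difference between these samples.

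Of 22523 probes, 6918 (30.7%) were detected on the Mock array and 7235 (32.1%) on the EA array. The median signal of detected probes was 409 on the Mock array and 403 on the EA array, 3.50 and 3.30 times the background level of 117 and 122. There were 5047 genes detected on both arrays, and their log2 signals correlated at Pearson r = 0.980 and Spearman rho = 0.972 across genes, which are not independent replicates. The median gene differed by -0.06 (log2, EA minus Mock), and 85.5% of genes lay within 0.5 of 0.

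Among the genes higher on the EA array were many immediate early genes, which are transcribed within minutes of a stimulus without new protein synthesis. Egr1, a zinc finger transcription factor, was 57.3-fold higher on the EA array, and Fos, a subunit of the AP-1 transcription factor, was 47.2-fold higher. Junb, another AP-1 subunit, was 12.5-fold higher, and the nuclear receptor Nr4a3 was 5.92-fold higher. The contractile genes of slow muscle fibres lay the other way, with Myh7, the slow myosin heavy chain, 12.1-fold lower and Tnnc1, the slow and cardiac troponin C, 9.48-fold lower. The authors' deposited values gave smaller folds for these genes, at 22.1 for Egr1, 17.7 for Fos, 7.86 for Junb, 3.15 for Nr4a3, 6.64 for Myh7 and 4.63 for Tnnc1. Of the 44 named genes past 2-fold, 15 had a fold more than 1.5 times smaller there, and besides these they were Dnajb1 at 11.3, Hmox1 at 4.06, Rpl30 at 7.54, Thrsp at 2.89, Postn at 2.63 and Col1a1 at 2.04, with Klf2, Sik1 and Tnmd at log2 differences of 1.58, 1.54 and -1.03. Several large folds rest on a signal near the detection floor, where their size depends on the background correction. On the Mock array Egr1 lay at 6.81, Fos at 6.72, Hmox1 at 6.64 and Nr4a3 at 5.87, against a floor of 5.79. On the EA array Tnnc1 lay at 6.13, against 5.66. Across all genes detected on both arrays, 105 were at least 2-fold higher on the EA array and 23 at least 2-fold lower, so 82.0% of these genes were higher. The counts were 49 and 8 without background correction, 47 and 7 with the deposited values, and 316 and 195, or 61.8% higher, at 1.5-fold. With the arrays scaled to their 75th percentile instead, which moved the median gene to 0.11, the counts were 177 and 14, or 92.7% higher. At 4-fold, 22 genes were higher and 4 lower.

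**Figure D1:**
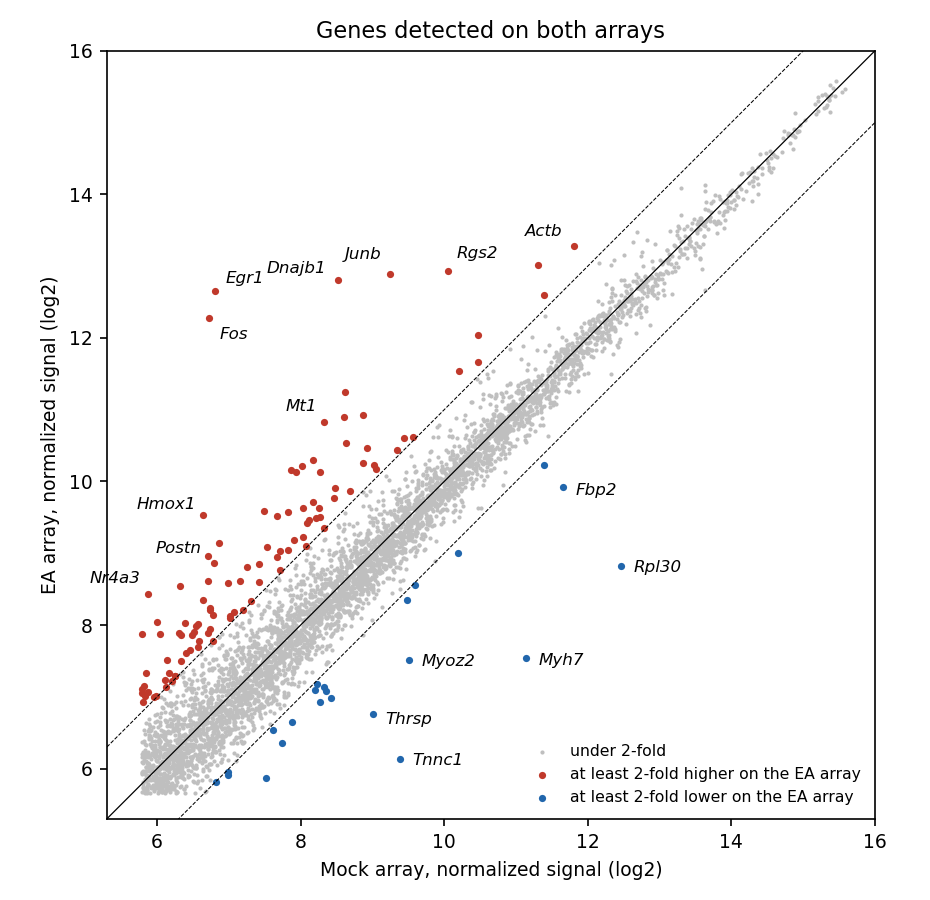
Normalized log2 signal of the 5047 genes detected on both arrays, Mock on the x axis and EA on the y axis, each point a gene, with dashed lines at 2-fold. Red points mark the 105 genes at least 2-fold higher on the EA array, among them Egr1 and Fos, and blue points the 23 at least 2-fold lower, among them Myh7 and Tnnc1.

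Of the 18 immediate early genes detected on both arrays, 13 were at least 2-fold higher on the EA array and none was 2-fold lower. Their median log2 difference was 1.88 (95% interval over members 0.95 to 2.62), at percentile 100 of the 10000 random lists. Egr2 was higher by 2.62, Klf4 by 2.29 and Klf2 by 2.28, as was Sik1, a salt-inducible kinase outside this list, by 2.26. The lowest members were Klf10 at 0.00 and Ier3 at -0.03. Among genes detected only on the EA array, Ier2 was at least 10.1-fold higher and Atf3, a stress-induced transcription factor, at least 9.84-fold higher. The chemokine genes Ccl2, Cxcl1 and Ccl7, which recruit leukocytes, were at least 8.37-fold, 5.17-fold and 4.96-fold higher by the same bound. These bounds move with the background: without background correction they were 3.85-fold for Ier2, 3.78-fold for Atf3, 3.32-fold for Ccl2, 2.31-fold for Cxcl1 and 2.24-fold for Ccl7.

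Genes of the stress response stood out singly rather than as lists. Dnajb1, a co-chaperone of Hsp70, was 19.6-fold higher on the EA array, Hsp90aa1, an inducible Hsp90 chaperone, 3.38-fold higher, and Hspb7, a small heat shock protein of muscle, 2.55-fold lower. The heat shock and chaperone list had a median of -0.07 (18 members, percentile 34.7). Hmox1, which breaks down haem, was 7.44-fold higher, the metal-binding Mt1 5.71-fold higher, and Ddit3, a transcription factor of endoplasmic reticulum stress, 4.94-fold higher. The oxidative and integrated stress list had a median of -0.10 (20 members, percentile 19.7). Rgs2, a regulator of G protein signalling, was 7.36-fold higher, and Coq10b, which takes part in coenzyme Q function, 4.38-fold higher.

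In MAP kinase signalling, the phosphatases Dusp1 and Dusp6, which switch MAP kinases off, were 3.25-fold and 2.54-fold higher on the EA array, while the list median was 0.05 (12 members, percentile 90.7). With the 1 member detected only on the EA array added at its lower bound, the median was 0.13 at percentile 99.2, although this member enters because it was detected on the EA array. The glucocorticoid-responsive list had a median of 0.11 (interval -0.22 to 1.54, 14 members) at percentile 98.8. Its members at least 2-fold higher numbered 4 and included Errfi1, an inhibitor of the EGF receptor, at 1.90 and Dusp1 at 1.70. The lowest members were Ddit4 at -0.58 and Klf15 at -0.42.

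Insulin signalling, the pathway by which muscle takes up glucose, had a median of -0.06 (interval -0.56 to 0.51, 11 members) and lay at percentile 50.2. No member detected on both arrays was 2-fold different. Akt2, the main Akt kinase of insulin-stimulated glucose uptake, differed by 0.80, the receptor substrate Irs1 by 0.51, and Akt1 by -0.11. Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, differed by -0.38 and the hexokinase Hk2 by -0.42. Gsk3b, a kinase that inhibits glycogen synthase, was lowest at -0.70, followed by the lipid phosphatase gene Inppl1 at -0.56. With the deposited values Akt2 differed by 0.49, Irs1 by 0.33 and Gsk3b by -0.46. Across the alternatives they ranged from 0.38 to 1.06, from 0.27 to 0.77 and from -0.70 to -0.40. Akt2 also lay near the detection floor on the Mock array, at 6.39 against 5.79. Insr and Irs2 were not detected on either array, and Pik3r1, Tbc1d4 and Gys1 had no named probe here. The values of Akt1, Slc2a4 and Hk2 lie within 0.48, the 95% half-width for a single probe if scatter with the SD of 0.25 is normal. Gaps between probes of a gene can be wider, as for Mettl7a at 0.82. A shift of 0.2 in a list of this size was found in only 49.5% of simulated lists of 12 genes.

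The list of AMPK and calcium signalling to glucose uptake had a median of 0.02 (14 members, percentile 78.4). Its highest members were Prkag3, an AMPK subunit of glycolytic muscle, at 0.79, with the gene's other probe at 0.74, and the AMPK kinase Stk11 at 0.59. The glycolysis and glycogen list had a median of -0.03 (22 members, percentile 69.3). In it Phkb, a subunit of phosphorylase kinase, was 2.49-fold higher and Ldhb, the lactate dehydrogenase subunit typical of oxidative muscle and heart, 2.29-fold lower. Fbp2, the muscle fructose-bisphosphatase, was 3.30-fold lower on the EA array.

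The genes of fatty acid uptake and oxidation had a median of -0.17 (interval -0.22 to -0.07, 26 members), at percentile 1.32, and 20 of the 26 lay below 0. Acadvl, which starts the oxidation of long-chain fatty acids, differed by -0.36 and the electron transfer gene Etfb by -0.50. Pdk4, which inhibits pyruvate dehydrogenase, went the other way at 2.90-fold higher. The list lay inside the central 95% of random lists with the deposited values, at percentile 2.98, and with random lists not matched on signal, at percentile 3.33. Scaled to the 75th percentile the median of this list was -0.04, against 0.11 for all genes. Oxidative phosphorylation had a median of -0.06 (26 members, percentile 32.0), with members from Ndufs1 at -0.30 to Ndufb8 at 0.22. In this list too, 20 of the 26 lay below 0, as did the median gene at -0.06. Above the median gene lay 7 members of the fatty acid list and 12 of the oxidative phosphorylation list. Thrsp, a regulator of fatty acid synthesis, was 4.71-fold lower, and G0s2, an inhibitor of the lipase ATGL, 1.95-fold lower.

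Slow fibre contractile genes had a median of -1.99 over 5 members detected on both arrays, below all of the random lists at percentile 0.00. Myoz2, a Z-disc protein of slow fibres, differed by -1.99 and Atp2a2, the slow and cardiac calcium pump, by -0.81, while Tpm3, which cells outside muscle also express, differed by 0.73. Myl3 and Tnnt1, the slow myosin light chain and troponin T, were detected only on the Mock array, and the bounds put Myl3 at least 8.48-fold lower on the EA array and Tnnt1 at least 2.58 lower on the log2 scale. Fast fibre contractile genes had a median of 0.00 (interval -0.05 to 0.06, 12 members, percentile 83.4). Of these, 8 lay within 1 log2 unit of the brightest signal, where saturation and rank-based normalization compress differences, and 3 had equal values on both arrays. Among the other 4, Myh2, the myosin of fast oxidative fibres, differed by -0.99 and Myh4, that of the fastest fibres, by 0.70. These myosins are close paralogs, so cross-hybridisation is possible. Tnnt3 and Cacng1, also among those 4 and named after their values were seen, differed by -0.05 and -0.01.

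Markers of cell types other than muscle fibres also differed. The fibroblast and matrix list had a median of 0.78 (interval 0.35 to 1.37, 18 members, percentile 100), with 8 members at least 2-fold higher on the EA array and 1 at least 2-fold lower, against 5 and 1 with the deposited values. Postn, a matrix protein of remodelling tissue, was 4.18-fold higher and Col1a1, a chain of type I collagen, 3.11-fold higher, while the tendon genes Tnmd and Fmod differed by -1.64 and -0.89. Endothelial markers had a median of 0.41 (interval 0.13 to 1.17, 9 members, percentile 99.9), led by Sox17 at 1.48 and the tight junction gene Cldn5 at 1.17. Only 1 endothelial member lay below 0, Egfl7 at -0.30. Erythrocyte markers had a median of 0.48 (interval -0.23 to 0.89, 6 members, percentile 99.96), with the globin genes Hbb-b1 at 0.89 and Hba-a1 at 0.79, which are paralogs that probes may not separate. The erythrocyte markers Gypc and Ahsp lay below 0, at -0.23 and -0.15. Macrophage and leukocyte markers had a median of 0.23 (interval 0.03 to 0.90, 11 members, percentile 98.4), with the complement genes C1qc at 0.98 and C1qb at 0.90. Schwann cell and nerve markers had a median of 0.59 at percentile 98.9, from only 3 members, of which Egr2 is also an immediate early gene. Without Egr2 the remaining members, Pmp22 at 0.59 and Cnp at -0.60, had a median of -0.01 at percentile 57.3, so that value rests on Egr2. No neutrophil marker was detected on both arrays, and 2 were detected only on the EA array.

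The other lists of cell types lay inside the central 95% of random lists. Adipocyte markers had a median of -0.02 (10 members, percentile 68.5) and smooth muscle and pericyte markers 0.03 (5 members, percentile 76.8), although Tagln, a smooth muscle actin-binding protein, was 2.26-fold higher. Cytosolic ribosomal proteins had a median of 0.05 (interval -0.04 to 0.12, 38 members) and lay at percentile 99.9. Rpl30, a ribosomal protein gene outside that list, was 12.4-fold lower on the EA array from its only probe, with none of the 38 listed ribosomal genes at 2-fold. Ribosomal protein genes have many pseudogene copies, which probes may not separate. The reference genes had a median of -0.02 (12 members, percentile 62.7), but Actb, the cytoskeletal actin often used to normalise expression, was 2.76-fold higher, with its other probes at 1.81 and 1.83 on the log2 scale.

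Of the remaining lists, atrophy and proteolysis had a median of 0.02 (21 members, percentile 90.5), with Mstn, an inhibitor of muscle growth, 2.52-fold higher and the ubiquitin ligase Fbxo32 at 0.80. Denervation and neuromuscular junction genes had a median of 0.14 (8 members, percentile 92.1), with the acetylcholine receptor subunit Chrne 2.71-fold higher. Both depend on the processing: with the deposited values Mstn was 1.78-fold and Chrne 1.88-fold higher, and their lowest alternatives were 0.57 and 0.81. Other named genes also fell short of 2-fold under at least 1 alternative, among them Sox17 at 0.88, Col1a1 at 0.90, Tagln at 0.59, Cldn5 at 0.92, Phkb at 0.95, Tnmd at -0.76, Ldhb at -0.76 and Hspb7 at -0.83. The circadian clock list had a median of -0.22 (8 members, percentile 6.69), from Per2 at -0.56 to Bhlhe40 at 0.13. Cytokines and inflammatory response had a median of 0.02 (6 members, percentile 68.5). A further 6 members were detected only on the EA array, among them Ccl2, Cxcl1 and Ccl7, and none only on the Mock array. With these at their lower bounds the median was 0.18 over 12 members at percentile 97.8, although these members enter because they were detected on the EA array. Interferon response and antigen presentation had a median of 0.10 (12 members, percentile 95.1), with the class I histocompatibility gene RT1-A2 4.26-fold higher. Myogenic and satellite cell genes had a median of 0.09 (9 members, percentile 92.6), and angiogenesis and hypoxia genes 0.07 (7 members, percentile 84.6). In all, 28 lists were measured, of which 8 lay above and 2 below the central 95% of random lists, where chance would put 1.4 of 28 outside, or more by the 7.5% found in simulation.

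**Figure D2:**
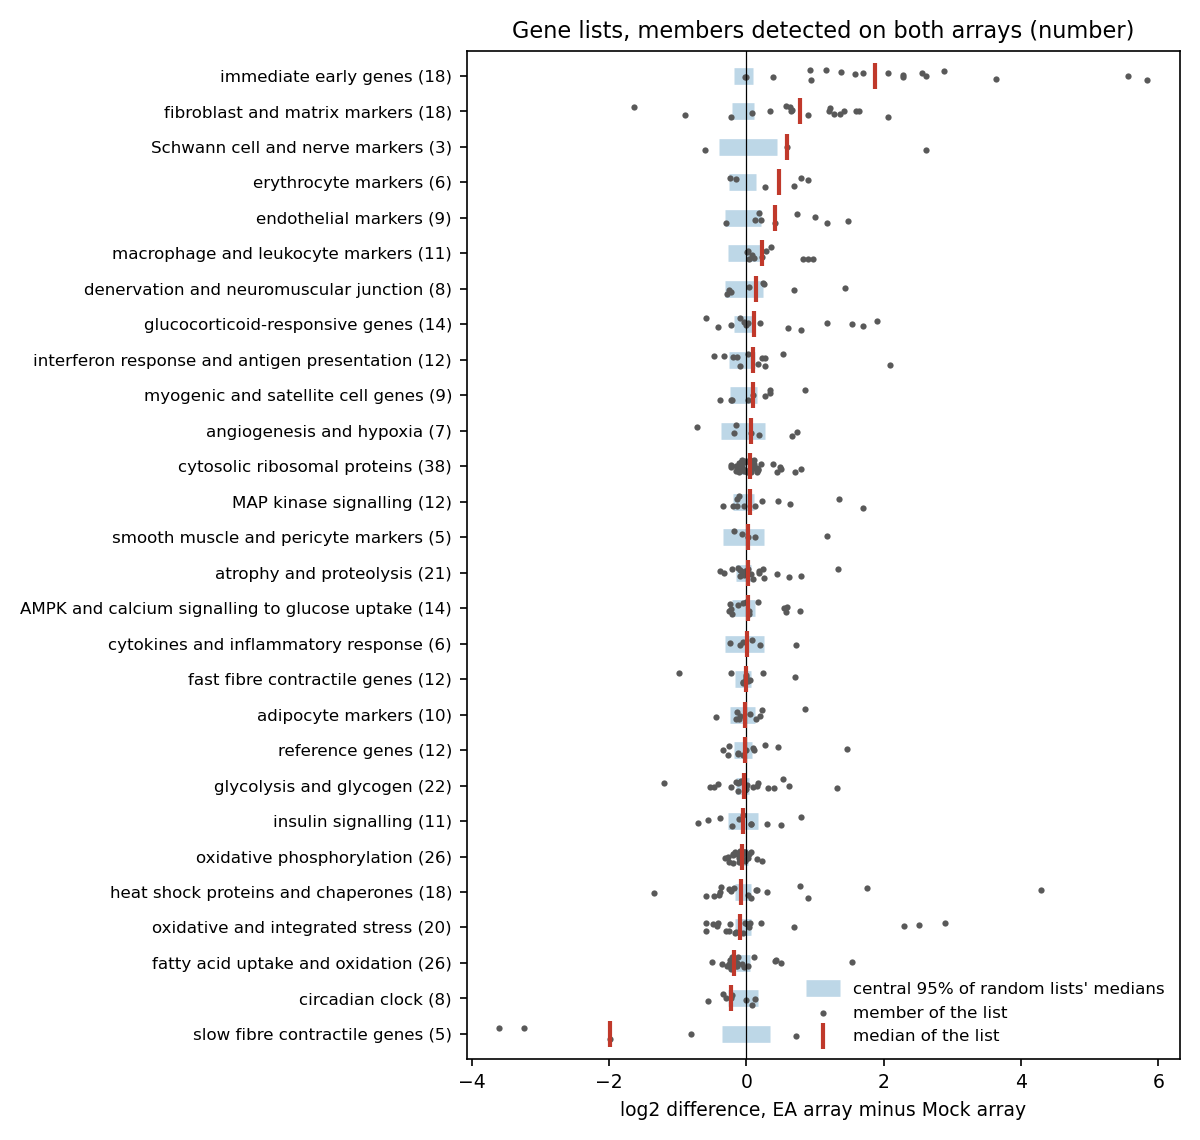
Log2 difference (EA array minus Mock array) of each member of the 28 measured gene lists, with grey points for members detected on both arrays, red bars for list medians and blue bands for the central 95% of the medians of 10000 signal-matched random lists. The immediate early list has its median at 1.88 and the slow fibre list at -1.99.

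Detection on only 1 of the arrays was seen for 412 genes on the EA array and 182 on the Mock array. The lower bound reached 2-fold for 25 of the former and 10 of the latter, and without background correction for 5 and 3. Besides the slow fibre genes, Rnase3 was at least 7.68-fold lower on the EA array, Rnf39 at least 2.92-fold and Nmrk1, a nicotinamide riboside kinase, at least 2.84-fold lower. Without background correction these bounds were 2.98-fold, 1.57-fold and 1.55-fold, and those of Myl3 and Tnnt1 were 3.22-fold and 2.48-fold.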

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

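No test here was planned, since the count was made after seeing that many probes carry no gene name. Of the probes without a gene name here, 1513 were detected on both arrays, and the comparisons by gene did not use them. Of these 1513 probes, 34 were at least 2-fold higher on the EA array and 8 at least 2-fold lower. Among the 5047 named genes the counts were 105 and 23, so the shares were similar and the unnamed probes did not stand out. The highest were ILMN_1356516 at 3.23 (log2, EA minus Mock) and ILMN_1376417 at 3.16, and the lowest ILMN_1362698 at -1.73 and ILMN_1369253 at -1.29. With 1 array per group, comparisons of a sample with the rest of its group could not be made.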

How the results depend on the processing

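Only the centred 75th percentile scaling, the Schwann cell list without Egr2, list members at their lower bound and bounds under other settings were chosen after seeing the data. No list outside the random range turned sign under a change of setting, except the Schwann cell list, at -0.0094 (percentile 57.3) without Egr2, and 302 of 309 alternative list medians stayed within the spread of the members. Without background correction, 49 genes were at least 2-fold higher and 8 lower, and with the authors' deposited values 47 and 7. All of these were among the 105 and 23. Background left in a signal shrinks differences by construction, and for the deposited values the cause was not tested. An offset of 50 gave 75 and 16. Scaling to the 75th percentile gave 177 and 14 and included all 105 higher genes. Centred on the median gene it gave 127 and 17, and cyclic loess gave 122 and 18. A 1.5-fold threshold gave 316 and 195, and the upper 50% of signals 43 and 7. At a detection p under 0.05 there were 123 higher and 35 lower genes, with 644 genes detected only on the EA array and 290 only on the Mock array. With no detection filter there were 153 higher and 47 lower genes. Normalization cannot move the detection counts, by construction. Scaling to the 75th percentile moved the median of oxidative phosphorylation to 0.046, fatty acid genes to -0.040, interferon response to 0.34, fast fibre genes to 0.16 and ribosomal proteins to 0.18, beside a shift of all genes to 0.11, and cyclic loess moved fast fibre genes to 0.056. Lists below the random range numbered 1 with the deposited values and 1 with unmatched random lists, and the cause was not tested. Over 12 settings with each list whole the immediate early, matrix, endothelial, erythrocyte and ribosomal lists stayed above the range and the slow fibre list below it. The glucocorticoid and Schwann cell lists were above in 11, the macrophage list in 9, and the fatty acid list below in 10. The MAP kinase and cytokine lists, inside the range otherwise, were above it in the 2 settings that add members detected on 1 array, and the interferon list in the 2 scaled to the 75th percentile. Neutrophil markers were above it in the 3 settings that measured any, from at most 2 members. In the settings that add members detected on 1 array, these markers enter because they were detected on the EA array. Of 938 alternative values of 134 named genes, 142 moved by more than the probe-pair SD, 127 of them toward 0. None of the 44 named genes past 2-fold turned sign, and 32 were past 2-fold in the deposited values. No paired analysis was possible because the groups share only replicate number 1, and with 1 array per group none can be left out. Detected signals stood at a median of only 3.50 and 3.30 times background, which limits small differences, and bead-level error was not run because the files used give no bead values.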

Other observations

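The tests of scaling, other cell types, slow fibre genes outside the contractile apparatus, connective tissue and marker lists against each other were chosen after results were seen, as were the gene families, each picked after a member had been seen, so their medians are not independent evidence. Time of day and the interval comparison of fast and slow lists were written down before their values were seen, except that clock genes near the detection floor were set aside afterwards. The rat major histocompatibility (RT1) genes, which present antigen, had a median of 0.34 over 14 genes detected on both arrays, with an interval of -0.05 to 1.09 over members, and 3 were at least 2-fold higher on the EA array. They were RT1-A2 at 2.09, RT1-M6-2 at 1.56 and RT1-T24-4 at 1.09, while RT1-DMb lay at -0.41. These genes are close paralogs that differ between rat strains, so the values of single members are uncertain. The collagen genes had a median of 1.21 over 10 genes, with 6 at least 2-fold higher, among them Col3a1 at 1.43 and Col14a1 at 1.30, and with Col7a1 at -0.28. Most of these collagens are also in the fibroblast and matrix list, so this is not separate evidence.

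Small heat shock (Hspb) genes had a median of -0.38 over 6 genes (interval -1.35 to 0.79), with Hspb7 lowest and Hspb1 at 0.79 the only 1 above 0, while the DNAJ co-chaperones had a median of -0.07 over 27 genes with only Dnajb1 at 2-fold. Krüppel-like factors had a median of 0.02 over 9 genes, of which 6 lay above 0, with Klf2 and Klf4 at 2-fold, Klf6 at 0.95 and Klf5 at -0.45. Dual-specificity phosphatases had a median of -0.17 over 11 genes, of which 4 lay above 0, with Dusp1 and Dusp6 at 2-fold.

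Immediate early genes were higher on the EA array. Their median stayed at least 1.498 above that of all genes under each of the 6 settings tried. The choice among these scalings and backgrounds therefore does not account for the gap. A scale factor shared by all genes cancels in this gap, so it was not tested here, and it could not make the gap either. A shifted time of day cannot be told apart: Dbp and Nr1d1 less Bmal1 differed by 0.088, and the limits written down beforehand were met, but Bmal1 and Dbp lie close to the detection floor, where a fall is compressed, and Per3, Tef and Npas2 were not detected. RNA from other cell types cannot be told apart, because the matrix list's median reaches 1.37 at its upper bound and the immediate early list's lower bound is 0.95, while 8 of the 18 immediate early genes exceed 2.06, the highest marker-list member other than Egr2, which both kinds of list hold; as top members they exclude nothing. Electroacupuncture, the handling of the animals and variation between animals stay open as untested, and with 1 array each they are confounded.

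Slow fibre contractile genes were lower on the EA array. The comparison of intervals written down beforehand decided nothing, because over 8 members detected on at least 1 array the upper bound for the slow list was 0.73, set by Tpm3, and the fast list's interval lies inside that range. A lower share of muscle RNA as the whole cause would lower other muscle genes about as far as the slow list's median of -1.99. The interval was -0.28 to 1.44 for the denervation and neuromuscular junction list and -0.23 to 0.35 for the myogenic list. Read after the values were seen, these argue against it as the whole cause for the genes they cover, although some lie near the detection floor. A smaller fall in the muscle share cannot be told apart. A comparison chosen after the values were seen asked whether markers of every other cell type rose alike. Of the 5 marker lists with an interval, the adipocyte list ended at 0.22, below the start of the matrix list's at 0.35. This speaks only against a lower share that raised all of them alike, since RNA from a single other tissue would raise only its own markers. In addition, 3 of the 10 adipocyte genes lie near the detection floor, some are also expressed in muscle, and a change in matrix itself stays open. Fewer slow fibres in the piece of muscle sampled cannot be told apart from lower expression, as 14 other genes of slow fibres had a median of -0.079 (interval -0.45 to 0.15), or -0.043 without Ldhb, which had been seen beforehand. A different part of the muscle or a different muscle, which the labels do not name, is a candidate explanation that was not tested, and electroacupuncture stays open too.

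Matrix genes were higher on the EA array. The list's median stayed at least 0.61 above that of all genes under 6 settings, so the choice among them does not account for the gap. As above, a scale factor shared by all genes cancels in this gap and was not tested. More connective tissue in the EA sample may account for it, as 83.3% of the members lay above the median gene, but this largely restates the pattern. The 2 members Tnmd and Fmod were lower by more than 0.48, the 95% half-width for a single probe given above. Connective tissue as a whole therefore did not move one way. More connective tissue, a different kind of it and higher expression cannot be told apart here.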
